A study of Zea mays with 18 samples.

How the data were processed

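The series profiled RNA from aleurone and starchy endosperm of maize (Zea mays) endosperm at 19 days after pollination, in the W22 background, for the genotypes R1-g, R1-sc and r1-m3, with 3 libraries of each compartment and genotype. Per the labels' protocols, plants were grown in the field and self-pollinated, the compartments were cut out by laser microdissection, RNA was isolated with the PicoPure kit, 5 ng of it was amplified to cDNA with the Ovation RNA-Seq System V2, and about 400 ng of cDNA went into paired-end NEBNext Ultra II libraries. The labels do not say whether an aleurone and a starchy endosperm library of the same number come from the same kernels. Amplified reads without molecular identifiers are not independent molecules, so floors and counting intervals cover counting error only.

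The deposited files are tables of read counts, 1 per library, with 46430 features and 5 HTSeq totals of reads given to no feature. Per the submitters' processing notes, the authors used Trimmomatic 0.39, FastQC, HISAT2, SAMtools, HTSeq 0.11.2 and DESeq2 with the genome build B73 RefGen_v4; the notes give no further settings, and the strand setting of the counting is not stated, so reads of overlapping and antisense features cannot be told apart. The counts are whole numbers without normalization. Table totals ranged from 42.1 to 69.2 M and feature totals from 12.5 to 20.4 M. Reads that aligned to several places took 42.2% to 55.0% of the table totals and were given to no feature, so members of families of near-identical genes are uncertain. Reads outside annotated features took 6.94% to 11.1%.

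Libraries were grouped by the genotype and compartment in their labels. Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr over the 6 groups kept 18028 features, TMM gave the scaling, and quasi-likelihood F tests with robust dispersion gave log2 fold changes, with p-values adjusted by Benjamini and Hochberg within each of 12 contrasts and called under 0.05. All 18 libraries entered 1 fit of 6 group means, which share an estimate of the spread. The contrasts were aleurone minus starchy endosperm in each genotype, each pair of genotypes in each compartment, and the 3 interactions. The SE of a log2 fold change was taken as its size divided by the square root of F. CPM values use TMM-scaled totals of the features tested, and correlations use log2 CPM with a prior count of 2. A fold against a group with 0 counts was computed against 3 counts over the whole group and is a lower bound. Shares of counts were compared between compartments by exact permutation of the libraries within genotypes; in a single comparison of 3 against 3 libraries such a test cannot go below 0.1.

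Choices made before the data were examined were the test, the groups, the named-feature rule, the gene lists and, with 4 exceptions below, the alternatives. The rule took features past the threshold whose 3 libraries of one group all lay above those of the other and whose mean reached 10 CPM. Of these it took the 8 named genes with the largest changes in each direction. Features without a name were not part of the planned rule. Of these, the 2 with the largest changes in each direction were taken, and the text gives some of them. In the interactions the libraries were not required to lie apart, and fewer features were taken than planned. The reference table of the assembly Zm-B73-REFERENCE-NAM-5.0 names 518 of the features, all of them organelle genes or microRNA precursors, and none of the nuclear gene models, which carry IDs of the older build. The planned gene lists, the level of r1, the compartment marker ratio and the test for calls near r1 on its chromosome need names or coordinates and were void. In their place, organelle genes were grouped by function from their symbols after the data had been seen, with plastid-derived copies in the mitochondrial genome left out, and tested beside the ENSRNA features with camera and fry of limma 3.58.1 for groups of at least 5 members (camera correlation 0.01, then estimated). These p-values were adjusted over the groups within a contrast.

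The scripts were tested on simulated counts drawn from the libraries' means, totals and dispersions with 200 features changed 8-fold or 64-fold. Chance overlap of comparisons that share libraries came from 20 simulations without any change; with 3 independent libraries per group, edgeR called a median of 12 and at most 25 features between r1-m3 and R1-g in the aleurone, and 4 and 12 in the starchy endosperm. For r1-m3 aleurone, 20 further simulations, added after the data had been seen, left out replicate 3. These 20 were also run with replicate 3 drawn as a weighted sum of replicates 1 and 2, about which its real counts scatter more widely. Other splits of the libraries were counted: all 10 of each comparison of 3 against 3, and 33 per interaction, the real one included. Alternatives were DESeq2 1.42.0, its size factors within edgeR, leaving the 50 most abundant features out of the scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, a fold change of at least 1 on the log2 scale, fits of only the libraries compared, a replicate block, and leaving out each library. Library totals without TMM factors, for calls and for organelle groups, nuclear gene models only, and r1-m3 aleurone replicate 3 left out of the spread of comparisons that do not hold it were added after the data had been seen. Means and SDs of r1-m3 aleurone leave out replicate 3, which the report describes, while the tests keep it.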

Results

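RNA-seq read counts were available for 18 libraries from laser-captured maize endosperm of the inbred line W22, taken 19 days after pollination. The libraries form 6 groups of 3, which combine the aleurone (the outermost endosperm cell layer) or the starchy endosperm (the storage tissue inside it) with the genotypes R1-g, R1-sc and r1-m3. R1 is a locus that controls anthocyanin pigment, and the series design gives R1-g as the wild type. Counts on annotated features, in mega-counts (M), ranged from 12.5 M in R1-sc starchy endosperm replicate 1 to 20.4 M in r1-m3 aleurone replicate 3. Mean feature totals were 15.5 ± 1.92 M in R1-g aleurone, 15.8 ± 0.587 M in R1-sc aleurone, 15.8 ± 1.36 M in R1-g starchy endosperm, 13.6 ± 1.47 M in R1-sc starchy endosperm and 16.6 ± 0.795 M in r1-m3 starchy endosperm (SD, n = 3 each), and 15.0 ± 0.221 M in r1-m3 aleurone replicates 1 and 2. Levels below are counts per M (CPM), scaled by TMM factors and given as mean ± SD, and floors and folds against a group without counts cover counting error only.

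Compartment set the libraries apart more than genotype did. The first dimension of the distances between libraries, with 29.8% of the variance, separated the aleurone from the starchy endosperm, and the second dimension held 6.38%. Across features, log2 CPM of an aleurone and a starchy endosperm library correlated at 0.371 to 0.454 over 81 pairs. Replicates of the same group correlated at 0.596 to 0.613 in R1-g aleurone and 0.571 to 0.601 in R1-sc aleurone, and at 0.747 to 0.822 within the starchy endosperm groups. Of 10248 features that reached 10 CPM in a library of R1-g aleurone, 2020 (19.7%) had 0 counts in another library of that group, and in R1-sc aleurone it was 23.2%. In the starchy endosperm the share was 4.59% in R1-g, 11.7% in R1-sc and 10.1% in r1-m3. The biological coefficient of variation was 1.44 in the aleurone and 1.24 in the starchy endosperm.

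**Figure D1:**
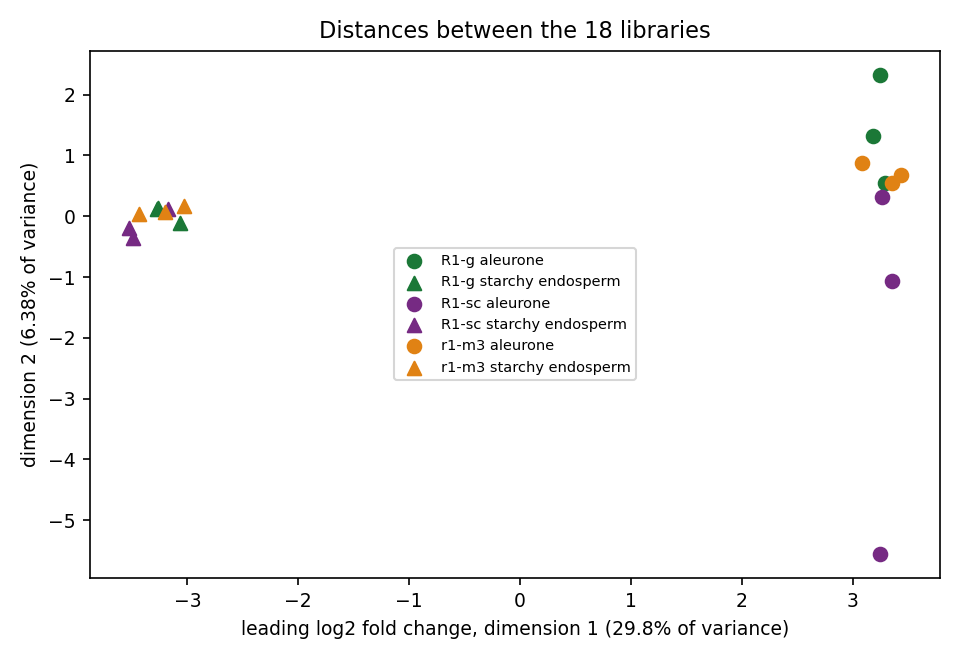
Distances between the 18 libraries as leading log2 fold changes, dimension 1 on the horizontal axis and dimension 2 on the vertical axis, with color for genotype and shape for compartment. Aleurone and starchy endosperm lie apart on dimension 1, which holds 29.8% of the variance, and R1-sc aleurone replicate 3 lies lowest on dimension 2.

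Replicate 3 of r1-m3 aleurone was not independent of replicates 1 and 2 by its counts. It held 490 of the 490 features that had 200 or more counts in 1 of replicates 1 and 2 and 0 in the other. In 60 sets of 3 aleurone libraries of the other genotypes, the corresponding share was 54.3% to 70.7%. The highest share in any set without r1-m3 aleurone, of sets with 100 or more such features, was 93.6%, in starchy endosperm libraries. Features with 200 or more counts in this library and 0 in both others of its group numbered 0, against 174 to 274 per library in R1-g and R1-sc aleurone. Replicates 1 and 2 correlated at 0.653 with each other, and at 0.872 and 0.892 with replicate 3. Its values are left out of every group mean and SD below (n = 2 in r1-m3 aleurone). The tests, planned before the data were examined, keep all 18 libraries. These share 1 estimate of the spread, so the p-values of every comparison count 1 library too many, and the counts of calls without it are given with the results.

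**Figure D2:**
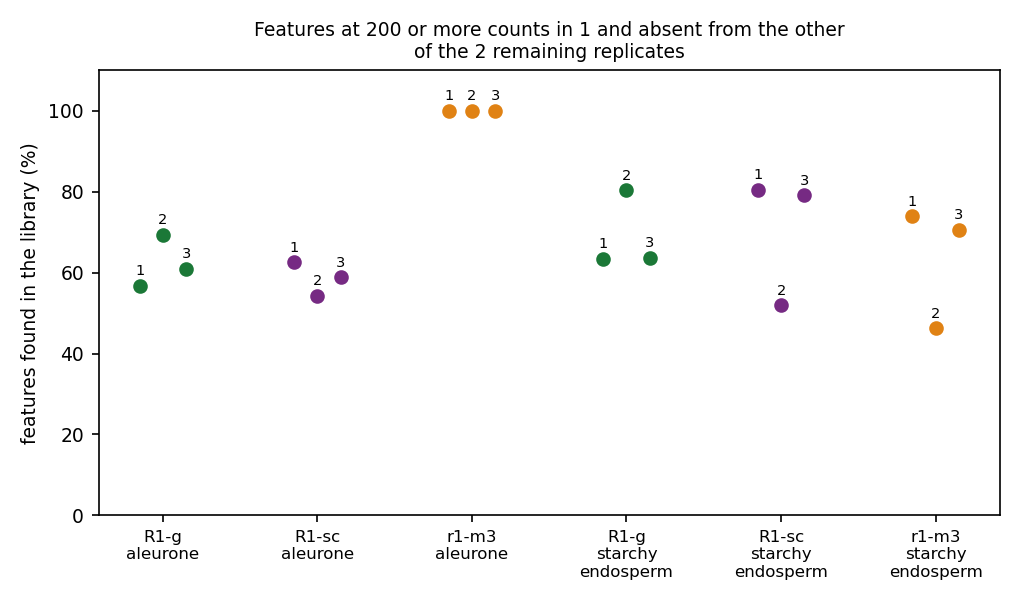
For each library, the percent of features found in it among those with 200 or more counts in 1 and 0 counts in the other of the remaining replicates of its group; points carry the replicate number. The 3 r1-m3 aleurone libraries lie at 100%, and every R1-g and R1-sc aleurone library lies under 70.7%.

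The aleurone libraries gave a larger share of their counts to organelle transcripts. Mitochondrial ribosomal RNA took 21.4 ± 3.51% of feature counts in the aleurone (n = 8) and 9.69 ± 1.29% in the starchy endosperm (n = 9). Mitochondrial protein-coding genes took 1.91 ± 0.199% against 0.610 ± 0.113%, and plastid genes 0.126 ± 0.0351% against 0.0271 ± 0.00926%. The 20 most abundant features together took 33.9 ± 4.62% of aleurone counts and 55.1 ± 1.74% of starchy endosperm counts. Reads outside annotated features took 10.02 ± 0.878% of the table totals in the aleurone and 7.55 ± 0.272% in the starchy endosperm, so the organelle shares did not move alone. For each of these 5 measures all 8 aleurone libraries lay on the same side of all 9 starchy endosperm libraries. A two-sided exact permutation test within genotypes over 4000 relabellings gave p = 0.00025 for each, the smallest it can give, and 0.000375 after adjustment over the 9 measures compared. Nuclear gene models took 63.3 ± 5.36% against 73.7 ± 2.95% (exact permutation p = 0.00025), with overlapping ranges. Features whose IDs begin with ENSRNA, for which the reference gives no name, took 13.2 ± 2.42% against 15.9 ± 2.56%, which did not pass after adjustment (exact permutation p = 0.045, adjusted 0.0506). Replicate 1 had the lowest ENSRNA share in all 6 groups, and the test does not pair libraries by number. Within same-numbered libraries of a genotype, r1-m3 replicate 3 included, the share was lower in the aleurone in 9 of 9 pairs. A difference is therefore not excluded. Reads that aligned to several places took 48.4 ± 3.29% of the table totals against 51.1 ± 1.92%, with overlapping ranges (exact permutation p = 0.0388, adjusted 0.0499). Features detected after thinning to equal depth numbered 14660 ± 1410 against 13620 ± 1287, a difference that did not pass (exact permutation p = 0.0705).

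**Figure D3:**
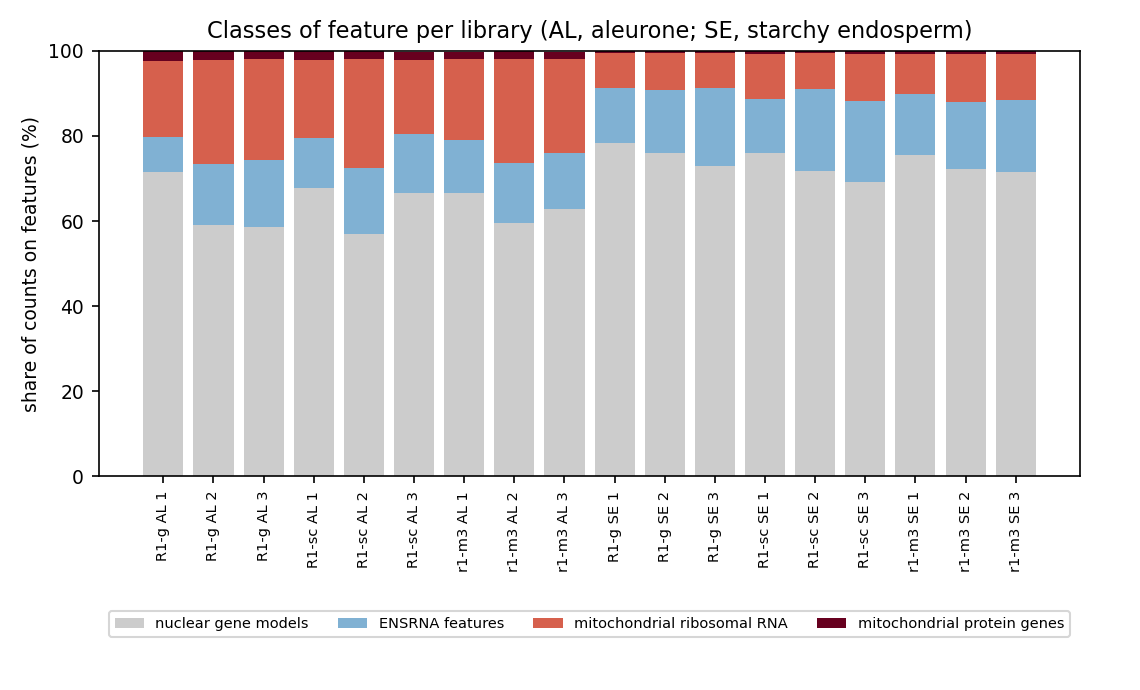
Share of feature counts per library, in percent, taken by nuclear gene models, ENSRNA features, mitochondrial ribosomal RNA and mitochondrial protein-coding genes, stacked; plastid genes and mitochondrial transfer RNA are too small to draw. Mitochondrial ribosomal RNA averages 21.4% in the aleurone and 9.69% in the starchy endosperm.

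The comparisons of aleurone with starchy endosperm ask which features mark each compartment. Of 3539 features called in at least 1 genotype, 1685 were called in 2 or more and 927 in all 3 in the same direction, of which 525 were higher in the aleurone and 402 higher in the starchy endosperm (910 and 231 when library totals were used without TMM factors). Independent lists of these sizes would share 6.45. Different genotypes called 1 feature in opposite directions, and the 3539 count it once for each direction. Of 176 organelle features tested, 27 were called in at least 1 genotype and 9 in all 3, and of the 27 only orf1159, in r1-m3, was lower in the aleurone. Of all 18028 features tested it was 3539 and 927. With both directions together, organelle features were thus not called more often than features in general. Higher in the aleurone alone, all 9 of 176 compare with 525 of 18028, a larger share. By genotype, 22, 16 and 11 organelle features were called higher in R1-g, R1-sc and r1-m3, against 880, 1496 and 1027 of all features. These are larger shares too, and the differences in share were not tested. The 9 were the plastid matK and 8 mitochondrial features, and 14 of their 27 calls were lost without some single library (adjusted p up to 0.153). Of the 9, only the mitochondrial orf107-b kept its call in all 3 genotypes whichever library was left out. Without r1-m3 aleurone replicate 3, 596 features were called in all 3 genotypes.

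In R1-g, 1784 of 18028 features differed between the compartments, 880 higher and 904 lower in the aleurone. Library totals without TMM factors gave 1584 higher and 594 lower, so the balance of directions depends on the scaling. The feature Zm00001d012572 stood at 1327 ± 148 CPM in the aleurone (n = 3) and had 0 counts in the starchy endosperm, a difference of at least 14880-fold with a floor of 3 counts over the group. In the other direction, Zm00001d045391 stood at 456 ± 38.6 CPM in the starchy endosperm and had 0 counts in the aleurone, at least 9509-fold lower. The organelle calls were 22, all higher in the aleurone, and 46 when library totals were used without TMM factors. Among them orf129-a stood at 209 ± 104 CPM against 1.90 ± 2.92 from 59 counts, of which 54 were in 1 library (log2 fold change 6.78, SE 1.49, edgeR adjusted p = 0.00379), and orf107-b stood at 75.1 ± 36.3 CPM against 1 count in all starchy endosperm libraries. As groups defined after the data were seen, the 80 mitochondrial open reading frames of no assigned function had a median log2 fold change of 2.85 and the 16 respiratory chain and ATP synthase genes of 1.34, where the median of all features tested was 0.38. Of the former, 10 were called over all features and 13 adjusted over the list alone. limma's camera set both groups apart from other features (adjusted p = 1.06e-08 and 0.000521), and with an estimated correlation this held for the open reading frames only (0.00598 and 0.117). The 9 mitochondrial ribosomal protein genes, with 4 called higher, had a median of 1.56 (camera adjusted p = 0.00467, 0.117 with an estimated correlation), and 3 of the 4 cytochrome c maturation genes were called higher. The 176 ENSRNA features, 32 of them called lower and 1 higher, had a median of -0.82 (camera adjusted p = 0.000521, 0.331 with an estimated correlation), which became 0.06 when library totals were used without TMM factors. The median of all features tested was then 1.31. The plastid groups had no called member: 17 ribosomal protein genes had a median of 1.19 (camera adjusted p = 0.0623) and 12 photosynthesis and NDH genes of 0.93 (0.291). The count of calls fell to 1076, 1138 and 1021 when starchy endosperm replicate 1, 2 or 3 was left out and to 1387 without r1-m3 aleurone replicate 3, and DESeq2 called 4518.

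In R1-sc, 2579 features differed, 1496 higher and 1083 lower in the aleurone (2337 and 725 without TMM factors). Zm00001d024303 stood at 3195 ± 1423 CPM in the aleurone (n = 3) and had 0 counts in the starchy endosperm, at least 30960-fold higher. Zm00001d010031 was 0 in the aleurone and stood at 600 ± 241 CPM in the starchy endosperm, at least 12080-fold lower. The 16 organelle calls (35 without TMM factors) were all higher in the aleurone and included the mitochondrial ccmFC, at 261 ± 97.5 CPM against 24.8 ± 6.03 and so 10.5-fold higher (log2 fold change 3.39, SE 0.635, edgeR adjusted p = 0.000683), and orf107-b, at 63.7 CPM against 0 counts and so at least 617-fold higher. The open reading frames had a median log2 fold change of 2.28, with 6 called over all features and 6 adjusted over the list alone (camera adjusted p = 0.000125, 0.0775 with an estimated correlation), against 0.59 for all features tested. The respiratory chain and ATP synthase genes had a median of 0.72 with 2 called (0.0366, and 0.316 with an estimated correlation), the ribosomal protein genes of 1.14 with 3 called (0.0605), and 2 of the 4 cytochrome c maturation genes were called higher. The ENSRNA features, 26 called lower and 1 higher, had a median of -0.86 (0.000125, and 0.316 with an estimated correlation). The plastid ribosomal protein genes had a median of 0.75 (0.383) and the photosynthesis and NDH genes of -0.61 (0.249), which turned to 0.30 without TMM factors. The median of all features tested was then 1.43. The count of calls fell to 1470, 1547 and 1428 when starchy endosperm replicate 1, 2 or 3 was left out and to 1942 without r1-m3 aleurone replicate 3, and it was 1423 from the 6 R1-sc libraries alone and 5665 with DESeq2.

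In r1-m3, 1788 features differed, 1027 higher and 761 lower in the aleurone (2010 and 434 without TMM factors). Zm00001d024303 stood at 1722 ± 245 CPM (n = 2) against 0 counts in the starchy endosperm, at least 20990-fold higher, and Zm00001d051288 at 0 counts against 596 ± 203 CPM (n = 3), at least 9102-fold lower. The plastid matK was 9.58-fold higher in the aleurone, at 832 ± 109 CPM (n = 2) against 86.8 ± 16.0 (log2 fold change 3.25, SE 0.516, edgeR adjusted p = 0.000113). The mitochondrial orf129-a and orf107-b were also called higher, at 98.6 ± 42.5 and 63.6 ± 15.2 CPM against 16 counts (10 in 1 library) and 6 counts (all in 1 library) in the starchy endosperm. In all, 11 organelle features were called higher and 1 lower, against 32 and 0 without TMM factors. The mitochondrial orf1159 was the organelle feature called lower (542 ± 101 CPM against 1266 ± 194, log2 fold change -1.24, SE 0.344, edgeR adjusted p = 0.0216). It was not called with library totals without TMM factors (0.757) or without a filter on low counts (0.0715). It was also not called without aleurone replicate 1 (0.0966), 2 (0.0532) or 3 (0.1) or starchy endosperm replicate 2 (0.0734) or 3 (0.0856). The open reading frames had a median log2 fold change of 2.07 against 0.62 for all features tested, with 7 called higher and 1 lower over all features and the same numbers adjusted over the list alone (camera adjusted p = 0.00188, 0.191 with an estimated correlation). The respiratory chain and ATP synthase genes had a median of 0.63 with 1 called (0.369), the ribosomal protein genes of 0.99 with 0 called over all features by edgeR, and 1 of the 4 cytochrome c maturation genes was called higher. The ENSRNA features, 33 called lower, had a median of -1.001 (1.14e-09, and 0.191 with an estimated correlation), which became 0.08 without TMM factors. The plastid ribosomal protein genes had a median of 0.65 (0.896) and the photosynthesis and NDH genes of -0.60 (0.214), which turned to 0.45 without TMM factors. The median of all features tested was 1.70 without these factors. Without aleurone replicate 3 the count of calls was 880, without replicate 1 or 2 it was 976 or 1000, and without starchy endosperm replicate 1, 2 or 3 it was 1028, 1009 or 1131. The 6 r1-m3 libraries alone gave 3946 and DESeq2 4730.

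**Figure D4:**
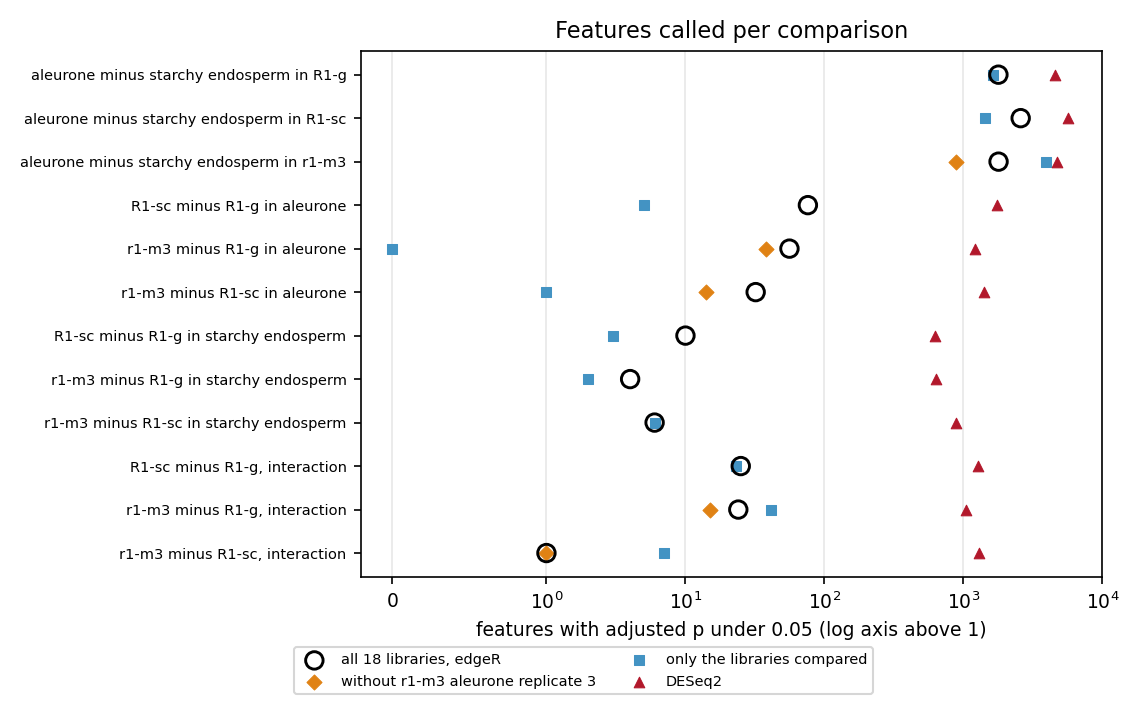
Features called per comparison at an adjusted p under 0.05, on a log axis above 1, from edgeR with all 18 libraries (open circles), without r1-m3 aleurone replicate 3 (diamonds), from only the libraries compared (squares) and from DESeq2 (triangles). The compartment comparisons call 1784 to 2579 features with edgeR, and the genotype comparisons 4 to 76.

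The genotype comparisons ask which features depend on the R1 allele within a compartment. The level of the r1 gene itself is not given, because neither the count tables nor the reference pair a feature ID with it. Whether a feature called between genotypes is r1 itself, Zm00001d026147 below included, is therefore not known. In the 6 genotype comparisons edgeR called 0 of the 176 organelle features, with 5 to 10 at an unadjusted p under 0.05 and 3 to 7 called by DESeq2. Camera placed some groups lower in r1-m3 aleurone, with replicate 3 kept. Against R1-g these were mitochondrial ribosomal protein genes (camera adjusted p = 0.0135), plastid photosynthesis and NDH genes (0.0277) and ENSRNA features (0.00248). Against R1-sc they were mitochondrial and plastid ribosomal protein genes (0.024 and 0.0389) and ENSRNA features (3.47e-07). None passed with an estimated correlation (0.201 to 0.393).

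In the aleurone, 76 features differed between R1-sc and R1-g, 51 higher and 25 lower in R1-sc. Zm00001d022032 stood at 85.4 ± 46.2 CPM in R1-sc (n = 3) and had 0 counts in R1-g, at least 1782-fold higher (log2 fold change 13.48, SE 2.34, edgeR adjusted p = 0.0109). Zm00001d043441 had 0 counts in R1-sc and stood at 118 ± 163 CPM in R1-g, at least 2381-fold lower (log2 fold change -13.95, SE 2.58, edgeR adjusted p = 0.00946), and it was not called without R1-g aleurone replicate 3 (adjusted p = 0.116). Of the 51 higher features, 29 were among those called higher in the starchy endosperm than in the aleurone of r1-m3, which hold 4.22% of all features tested. Such features made up 46.1% of the 76 calls, 25.6% of the 172 calls from wrong splits of these libraries, which keep part of any genotype difference, and 67.1% of the 167 calls in 20 simulations of unchanged genotypes. The 6 aleurone libraries alone gave 5 calls, with neither of these IDs (adjusted p = 0.0555 and 0.11), and DESeq2 gave 1743, and without R1-sc replicate 2 the count was 125. Without r1-m3 aleurone replicate 3 in the estimate of the spread it was 54. The 20 simulations of unchanged genotypes, with 3 independent libraries per group, gave a median of 7 and at most 17 calls here. Both 76 and 54 lie above that, while wrong splits of the libraries gave up to 44 calls. In simulated counts for this comparison, edgeR recovered 10 of 100 features changed 8-fold and 35 of 100 changed 64-fold, and 21 of its 66 calls were features left unchanged.

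Between r1-m3 and R1-g aleurone, 56 features differed, 46 higher and 10 lower in r1-m3. Zm00001d001953 stood at 21.4 ± 18.9 CPM in r1-m3 (n = 2) and had 0 counts in R1-g, at least 446-fold higher (log2 fold change 11.40, SE 1.25, edgeR adjusted p = 1.79e-05). Zm00001d014914 had 0 counts in r1-m3 and stood at 74.4 ± 47.0 CPM in R1-g (n = 3), at least 1136-fold lower (log2 fold change -13.28, SE 1.39, edgeR adjusted p = 3.13e-05). Of the 46 higher features, 36 were among those called higher in the starchy endosperm than in the aleurone of R1-sc, which hold 6.01% of all features tested, but such features made up 73.2% of the 56 calls, 57.1% (4 of 7) of the calls from wrong splits and 62.3% of the 252 calls in the simulations. Without r1-m3 aleurone replicate 3 there were 38 calls, where 20 simulations of unchanged genotypes without that library gave a median of 21 and at most 32. With replicate 3 drawn as a weighted sum of replicates 1 and 2, the simulations gave a median of 62 and at most 95. The 56 calls are not above that. Real counts of replicate 3 scatter more widely about the sum, so these draws can overstate its dependence and do not decide on the 56. The 38 calls without replicate 3 lay above the 32 of the highest draw without it. edgeR on the 6 aleurone libraries alone called 0, with 1505 features at an unadjusted p under 0.05 and adjusted p = 0.246 and 0.231 for these IDs, and DESeq2 called 1212.

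Between r1-m3 and R1-sc aleurone, 32 features differed, 20 higher and 12 lower in r1-m3. Zm00001d014914 again had 0 counts in r1-m3, against 360 ± 29.9 CPM in R1-sc (n = 3), at least 5500-fold lower (log2 fold change -15.56, SE 1.46, edgeR adjusted p = 1.06e-05). Zm00001d044122 had 0 counts in r1-m3 and 411 ± 254 CPM in R1-sc, at least 6278-fold lower (edgeR adjusted p = 0.0018). Zm00001d033484 stood at 31.7 ± 31.8 CPM in r1-m3 (n = 2) and had 0 counts in R1-sc, and it was not called without r1-m3 replicate 1 or 3 or R1-sc replicate 3 (adjusted p up to 0.0597). Without r1-m3 aleurone replicate 3 there were 14 calls, without r1-m3 replicate 2 there were 20, and without R1-sc replicate 1 or 2 there were 67 or 56. The 6 aleurone libraries alone gave 1 call, which was Zm00001d014914 (for Zm00001d044122 adjusted p = 0.0569, for Zm00001d033484 0.212), and DESeq2 gave 1415. Of the 20 higher features, 14 were called higher in the starchy endosperm of R1-g; such features made up 53.1% of the 32 calls, 60% of the 20 calls from wrong splits and 70.9% of the 165 calls in the simulations. The 14 calls without replicate 3 are not above chance, since the simulations without that library gave a median of 20 and at most 40. With replicate 3 drawn as a weighted sum of replicates 1 and 2 they gave a median of 65 and at most 95. The 32 calls are not above that either, but these draws can overstate the dependence of replicate 3 and do not decide on the 32.

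In the aleurone, 15 features were called in r1-m3 against both other genotypes in the same direction, 10 higher and 5 lower. Independent lists would share 0.0510 higher and 0.00666 lower. Both comparisons use the same r1-m3 libraries, so chance alone shares more. All 10 higher features were also called higher in the starchy endosperm than in the aleurone of R1-g and of R1-sc, and 8 of them in all 3 genotypes, at 24.8 to 14400 CPM in the starchy endosperm; these calls share their low aleurone libraries with the genotype comparisons, so the 2 sets of calls are not independent. Without r1-m3 replicate 3 the number was 9, where 20 simulations of unchanged genotypes without that library gave a median of 5.5 and at most 11, so the 9 are not above chance. Without R1-g replicate 3 the number was also 9. With r1-m3 replicate 3 drawn as a weighted sum of replicates 1 and 2, simulated calls shared a median of 25.5 and at most 42 features. The 15 are not above that, but these draws can overstate the dependence of replicate 3 and do not decide on the 15. In the starchy endosperm 1 feature was shared, lower in r1-m3, where the simulations gave a median of 0 and at most 2; it was 0 without R1-sc replicate 1 and without r1-m3 replicate 1 or 3, and 2 without R1-sc replicate 2.

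In the starchy endosperm, 10 features differed between R1-sc and R1-g, 1 higher and 9 lower in R1-sc. The higher feature was Zm00001d026147, with 0 counts in the 3 R1-g libraries and 263.5 ± 20 CPM in R1-sc (n = 3), at least 2954-fold higher (log2 fold change 15.11, SE 1.37, edgeR adjusted p = 1.23e-06). It was called under every alternative and without any 1 of the 6 libraries. Zm00001d034713 stood at 1.14 ± 0.778 CPM in R1-sc and 24.4 ± 26.4 CPM in R1-g, 21.4-fold lower (log2 fold change -4.41, SE 0.776, edgeR adjusted p = 0.0237), and it was not called without R1-g replicate 1 or R1-sc replicate 1 or 2 (adjusted p up to 0.271), from the 6 libraries alone (0.568) or with a replicate block (0.0539). As groups, the 12 plastid photosynthesis and NDH genes were higher in R1-sc, with a median log2 fold change of 0.57 and 11 of 12 positive (camera adjusted p = 0.000416, 0.0305 with an estimated correlation), and so were the 80 mitochondrial open reading frames, with a median of 0.38 and 51 positive (1.67e-05, and 0.0305). fry, which tests whether genes move one way, gave 0.0292 for the former and 0.0976 for the latter, and no member of either was called by edgeR. By camera the plastid ribosomal protein genes (adjusted p = 0.000388) and the ENSRNA features (7.96e-05) were higher too, but not with an estimated correlation (0.105 and 0.246). The count of calls was 6, 2, 3, 17 and 4 without R1-g replicate 1, R1-sc replicate 1, R1-sc replicate 2, R1-g replicate 3 and R1-sc replicate 3 and 5 without r1-m3 aleurone replicate 3, and DESeq2 called 620. In simulated counts for this comparison, edgeR recovered 11 of 100 features changed 8-fold and 68 of 100 changed 64-fold, and 11 of its 90 calls were unchanged.

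Between r1-m3 and R1-g starchy endosperm, 4 features differed, 1 higher and 3 lower in r1-m3. The higher feature was again Zm00001d026147, at 349.5 ± 74.0 CPM in r1-m3 (n = 3) against 0 counts, at least 3918-fold higher (log2 fold change 15.51, SE 1.37, edgeR adjusted p = 8.22e-07), and it was called under every alternative and without any 1 of the 6 libraries. In R1-g aleurone the same feature was present at 43.1 ± 31.8 CPM. By camera, 2 mitochondrial groups were higher in r1-m3: the open reading frames (adjusted p = 0.000174) and the respiratory chain and ATP synthase genes (0.00469). So were the plastid photosynthesis and NDH genes (0.0178) and the plastid ribosomal protein genes (0.0244). With an estimated correlation none passed (0.0642, 0.195, 0.15 and 0.291). The count of calls was 11 without R1-g replicate 1 and 10 without R1-g replicate 3, and 4 without r1-m3 aleurone replicate 3, and DESeq2 called 637. A count of 4 is not above chance: 20 simulations of unchanged genotypes gave a median of 4 and at most 12 calls in this comparison.

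Between r1-m3 and R1-sc starchy endosperm, 6 features differed, 4 higher and 2 lower in r1-m3. Zm00001d013956 was 11.3-fold lower in r1-m3 than the 1393 ± 727 CPM of R1-sc (n = 3 each; log2 fold change -3.50, SE 0.512, edgeR adjusted p = 0.0053), and it was called under every alternative and without any 1 of the 6 libraries. Zm00001d034713 was 22.6-fold higher in r1-m3, at 25.7 ± 10.6 CPM against 1.14 ± 0.778 (log2 fold change 4.48, SE 0.779, edgeR adjusted p = 0.0264), and was not called without R1-sc replicate 1 or 2 (adjusted p up to 0.129) or from the 6 libraries alone (0.52). The count of calls was 1, 3, 12 and 19 without R1-sc replicate 1, r1-m3 replicate 1, R1-sc replicate 2 and r1-m3 replicate 2, and 5 without r1-m3 aleurone replicate 3, and DESeq2 called 879.

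Whether a genotype difference depended on the compartment was tested by the interaction. Between R1-sc and R1-g, 25 features differed in this way, 23 with a higher and 2 with a lower difference of aleurone minus starchy endosperm in R1-sc. Between r1-m3 and R1-g the numbers were 24, 20 and 4, and between r1-m3 and R1-sc 1 feature was called, higher in r1-m3. Wrong splits of the libraries gave up to 32, 25 and 22 calls in these comparisons, so chance is not excluded for the counts. The 25 became 39, 45 and 16 without R1-sc aleurone replicate 1, R1-sc aleurone replicate 2 and R1-sc starchy endosperm replicate 1. The 24 became 10, 14 and 13 without r1-m3 starchy endosperm replicate 1, 2 and 3, and 15 without r1-m3 aleurone replicate 3 or R1-g starchy endosperm replicate 2. The 1 became 11, 12 and 3 without R1-sc aleurone replicate 1, 2 and 3, 2 and 7 without R1-sc starchy endosperm replicate 1 and 2, 7 and 3 without r1-m3 aleurone replicate 1 and 2, and 3 without r1-m3 starchy endosperm replicate 2. Without r1-m3 aleurone replicate 3 the 25 became 23 and the 1 stayed 1. The group tests that follow keep r1-m3 aleurone replicate 3 where r1-m3 enters. Between R1-sc and R1-g, the compartment difference of the plastid photosynthesis and NDH genes was lower in R1-sc by a median log2 of -1.63 (camera adjusted p = 0.0077, 0.123 with an estimated correlation, fry 0.00736). Between r1-m3 and R1-g, that of the plastid photosynthesis and NDH genes was lower in r1-m3 by -1.28 (camera adjusted p = 0.000671, 0.033 with an estimated correlation). That of the mitochondrial open reading frames was lower by -0.73 (0.000193, and 0.033), and fry gave 0.018 for the former and 0.195 for the latter. Every other group tested, the ENSRNA features included, was also lower by camera (adjusted p = 0.00054 to 0.0127), but not with an estimated correlation (0.132 to 0.25). edgeR called 0 organelle features in the interactions, with 5 to 9 at an unadjusted p under 0.05 and 3 to 4 called by DESeq2.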

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

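The tests of this part were chosen before the data were examined. They test whether the difference between genotypes itself differs between the compartments, by edgeR's interaction of genotype and compartment.

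Between R1-sc and R1-g, 25 features differed in this way (2160 at an unadjusted p under 0.05, 1268 with DESeq2). Of 33 splits of the libraries, 3 gave as many calls with the real one counted, and the highest other count was 32, so chance is not excluded for this count. The count was 39 without R1-sc aleurone replicate 1, 45 without R1-sc aleurone replicate 2 and 16 without R1-sc starchy endosperm replicate 1, and 23 without r1-m3 aleurone replicate 3, which enters the estimate of the spread. Zm00001d036608 had a log2 interaction of 12.71 (SE 1.33, edgeR adjusted p = 2.12e-05): it had 0 counts in R1-g aleurone and 49.9 ± 46.4 CPM in R1-sc aleurone, with 414 ± 160 and 412.5 ± 162 CPM in the starchy endosperm (n = 3 each). Zm00001d002708 (12.12, SE 2.37, adjusted p = 0.0258) went from 0 counts to 30.1 ± 19.6 CPM in the aleurone, with 34.1 ± 17.6 and 30.9 ± 22.6 CPM in the starchy endosperm, and lost its call without any 1 of 7 libraries: the 3 of R1-g aleurone, the 3 of R1-sc starchy endosperm and R1-g starchy endosperm replicate 1 (adjusted p up to 0.122), with a replicate block (0.0543) and without TMM factors (0.0624). Zm00001d026147 had -12.86 (SE 1.49, adjusted p = 7.73e-05): in the starchy endosperm it went from 0 counts in R1-g to 263.5 ± 20 CPM in R1-sc, and in the aleurone from 43.1 ± 31.8 to 204 ± 176 CPM. Zm00001d002087 had -8.26 (SE 1.64, adjusted p = 0.0258), with 7.56 ± 6.85 CPM in R1-g aleurone and 1 count in R1-sc aleurone, against 91.6 ± 23.4 and 89.0 ± 62.8 CPM in the starchy endosperm, and lost its call without any 1 of 8 libraries: aleurone replicate 1 of R1-g and replicates 1 and 2 of R1-sc, the 3 of R1-g starchy endosperm and R1-sc starchy endosperm replicates 1 and 3 (adjusted p up to 0.112), with a replicate block (0.0543) or one within genotype (0.084), without TMM factors (0.0624) and from the 12 libraries alone (0.134).

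Between r1-m3 and R1-g, 24 features differed in this way (1946 at an unadjusted p under 0.05, 1045 with DESeq2). Of 33 splits, 2 gave as many calls with the real one counted, and the highest other count was 25, so chance is not excluded. The count was 15 without r1-m3 aleurone replicate 3, 10, 14 and 13 without r1-m3 starchy endosperm replicate 1, 2 and 3, and 15 without R1-g starchy endosperm replicate 2. Zm00001d032508 had a log2 interaction of 12.86 (SE 2.42, adjusted p = 0.0238), with 0 counts in R1-g aleurone and 40.5 ± 34.6 CPM (n = 2) in r1-m3 aleurone, against 32.1 ± 18.6 and 22.9 ± 20.1 CPM in the starchy endosperm, and lost its call without any 1 of 8 libraries: the 3 of R1-g aleurone, the 3 of r1-m3 starchy endosperm, r1-m3 aleurone replicate 1 and R1-g starchy endosperm replicate 2 (adjusted p up to 0.0816). Zm00001d001953 had 11.09 (SE 1.42, adjusted p = 0.000209), with 0 counts against 21.4 ± 18.9 CPM in the aleurone and 144 ± 36.6 against 178 ± 80.1 CPM in the starchy endosperm. Zm00001d026147 had -13.20 (SE 1.5, adjusted p = 6.42e-05), from 0 counts to 349.5 ± 74.0 CPM in the starchy endosperm and from 43.1 ± 31.8 to 221 ± 79.1 CPM in the aleurone. Zm00001d033322 had -8.77 (SE 1.70, adjusted p = 0.0259), with 12.2 ± 14.3 CPM in R1-g aleurone and 0.0822 ± 0.116 in r1-m3 aleurone, against 65.5 ± 18.9 and 142 ± 34.3 CPM in the starchy endosperm, and lost its call without any 1 of 7 libraries: r1-m3 aleurone replicates 2 and 3, R1-g aleurone replicate 3, the 3 of R1-g starchy endosperm and r1-m3 starchy endosperm replicate 1 (adjusted p up to 0.108) and without TMM factors (0.0607).

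Between r1-m3 and R1-sc, 1 feature was called (2121 at an unadjusted p under 0.05, 1284 with DESeq2). Of 33 splits, 17 gave as many calls, and the highest other count was 22, so chance is not excluded for the count. It was 11, 12 and 3 without R1-sc aleurone replicate 1, 2 and 3, 2 and 7 without R1-sc starchy endosperm replicate 1 and 2, 7, 3 and 1 without r1-m3 aleurone replicate 1, 2 and 3, and 3 without r1-m3 starchy endosperm replicate 2. The feature was Zm00001d045391, with a log2 interaction of 7.49 (SE 0.880, adjusted p = 0.000387). It had 0 counts in R1-sc aleurone and 2.19 ± 0.595 CPM in r1-m3 aleurone (n = 2), against 333 ± 59.3 and 569.7 ± 111 CPM in the starchy endosperm (n = 3 each), and it kept its call without any 1 of the 12 libraries (adjusted p up to 0.0023).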

How the results depend on the processing

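The 15 counts of calls were recomputed under 289 alternatives, of which 188 stayed within 1.5 times the reported count and 101 did not. Named genes and IDs kept their call in 948 comparisons with an alternative and lost it in 139, and 0 reversed. Of the organelle and ENSRNA group results, 88 held, 7 newly passed, 10 no longer passed and 5 reversed in the sign of the median or the direction of the test. The cause was not tested unless it is named.

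DESeq2 called more features than edgeR throughout, and the cause was not tested: 4518, 5665 and 4730 between the compartments of R1-g, R1-sc and r1-m3, with 2004 in all 3. It called 1743 (R1-sc minus R1-g), 1212 (r1-m3 minus R1-g) and 1415 (r1-m3 minus R1-sc) in the aleurone, 620, 637 and 879 in the starchy endosperm, and 1268, 1045 and 1284 interactions. Calls of r1-m3 against both other genotypes were 397 in the aleurone and 324 in the starchy endosperm.

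Fits of only the libraries compared have fewer libraries and their own spread. They called 1423 features between the compartments of R1-sc, 3946 in r1-m3 and 594 in all 3 genotypes. In the aleurone they called 5 (R1-sc minus R1-g), 0 (r1-m3 minus R1-g; 1505 at an unadjusted p under 0.05, 1212 with DESeq2) and 1 (r1-m3 minus R1-sc), with 0 for r1-m3 against both. In the starchy endosperm they called 3 (R1-sc minus R1-g) and 2 (r1-m3 minus R1-g), and the interactions of r1-m3 gave 41 (against R1-g) and 7 (against R1-sc). Without a filter on low counts there were 413, 245 and 219 calls in the aleurone, 101, 95 and 170 in the starchy endosperm, and 257, 208 and 241 interactions, in the same order, with 70 and 48 for r1-m3 against both.

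With the replicate number as a block, the counts that moved by over 1.5 times were 46 (R1-sc minus R1-g) and 21 (r1-m3 minus R1-sc) in the aleurone and 2 and 2 in the starchy endosperm, with 0 for r1-m3 against both in the starchy endosperm (1 without the block, 324 with DESeq2). A replicate block within genotype gave 37 and 17 interactions of r1-m3 against R1-g and R1-sc. Same-numbered libraries of a genotype did not deviate together across features (correlations of -0.001 to 0.021), but replicate 1 had the lowest ENSRNA share in all 6 groups, so a shared effect of the number is not ruled out.

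DESeq2's size factors in edgeR gave 6 calls (R1-sc minus R1-g) and 11 (r1-m3 minus R1-sc) in the starchy endosperm, and a filter of 1 CPM gave 11 for the latter. They moved the median log2 fold change between compartments by 0.09 to 0.24. Library totals without TMM factors, chosen after seeing the data, moved it by 0.78 to 1.06 and the calls to 1584 higher and 594 lower in R1-g (880 and 904 with TMM), 2337 and 725 in R1-sc (1496 and 1083), and 2010 and 434 in r1-m3 (1027 and 761). They gave 910 higher and 231 lower in all 3 genotypes (525 and 402 with TMM), 13 calls between r1-m3 and R1-sc starchy endosperm, and 6 higher and 5 lower for r1-m3 against both in the aleurone (10 and 5). They reversed the sign of the median of the ENSRNA features in R1-g (0.064) and r1-m3 (0.076). The same held for the plastid photosynthesis and NDH genes in R1-sc (0.303) and r1-m3 (0.454). The median of all features tested rose too, to 1.308 in R1-g, 1.434 in R1-sc and 1.702 in r1-m3. These groups therefore still lay below it, and camera was not rerun without TMM factors. Under fry the plastid ribosomal protein genes of r1-m3 (median 0.65) went up, where camera, which compares with other features, went down. Nuclear gene models alone gave 2 interactions between r1-m3 and R1-sc.

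Leaving out 1 library at a time gave 1021 to 1471 calls between compartments in R1-g, 1428 to 2123 in R1-sc, 880 to 1131 in r1-m3 and 645 to 848 in all 3. Leaving r1-m3 aleurone replicate 3 out of the spread of every comparison, chosen after seeing the data, gave 596 in all 3 and 5 between R1-sc and R1-g starchy endosperm. Omitting 1 library of the comparison at a time gave, in the aleurone, 84 to 125 (R1-sc minus R1-g), 38 to 67 (r1-m3 minus R1-g) and 14 to 67 (r1-m3 minus R1-sc). In the same order it gave 2 to 17, 4 to 11 and 1 to 19 in the starchy endosperm, and 16 to 45, 10 to 25 and 1 to 12 interactions. Calls of r1-m3 against both ranged from 9 to 15 in the aleurone and 0 to 2 in the starchy endosperm. The report and the interaction results name the libraries behind moves of over 1.5 times. Alternatives for gene lists, chromosome windows and the marker ratio were not run, since those results were void. Depth limits features near 3 counts over a group. Of 100 simulated 8-fold changes, 10 were recovered in the aleurone and 11 in the starchy endosperm.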

Other observations

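Chosen after the result was seen were the tests on r1-m3 aleurone replicate 3 and those on the features called higher in R1-sc or r1-m3 aleurone. The tests of carry-over and scaling on those features were added after the planned tests had left both open. Limits of the planned scaling test were narrowed after its value was seen, and a test of detected features against depth was dropped. The share of abundant starchy endosperm features that rose, the difference of medians for scaling, and the tests on feature numbers and on splits of the libraries were planned.

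In r1-m3 aleurone, replicate 3 held the features of replicates 1 and 2 together. A candidate explanation is that it mixes material or reads of both: it held 100% of the 490 features present in only 1 of them (at most 93.6% in any set of libraries without r1-m3 aleurone), at a median of 0.581 of the replicate 1 count for 272 features and 0.774 of the replicate 2 count for 218. Greater depth is excluded, since the share was also 100% after thinning to 12.5 M counts. A lower spread in this group is not the whole account: replicates 1 and 2 correlated at 0.653 with each other, and at 0.872 and 0.892 with replicate 3. Some lower spread stays open, since the 0.653 lies above the 0.571 to 0.613 within R1-g and R1-sc aleurone. Plain addition of the sequenced reads is excluded too, since squared deviations from the weighted sum had a median of 2.54 where counting error gives 0.455, so a mixture of material, or of reads in another way than addition, stays open. No biological explanation was tested.

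Of the features called higher in R1-sc or r1-m3 aleurone than in R1-g aleurone, 29 of 51 and 36 of 46 were features of the starchy endosperm, which made up 46.1% and 73.2% of all calls in these comparisons, and 67.1% and 62.3% of the calls in simulations of unchanged genotypes. Starchy endosperm RNA carried into the captures in the proportions of the captured tissue would bring the same share of every abundant transcript. The median rise of the called features was 11.8% and 5.65% of the starchy endosperm level. Of 49 abundant features (1000 CPM or more), 5 in R1-sc and 3 in r1-m3 lay over 10 times below it, at 0.0569% to 0.719% and 0.175% to 0.468%. This argues against carry-over in those proportions as the source of a rise of that size. The called features were picked for a high value in the same comparison, which inflates their rise. A smaller carry-over, or one in other proportions, therefore stays open for them. For the smaller rise of abundant features in general it stays open too, since 77.6% were higher in R1-sc aleurone, between the limits set for and against it. For the called features, a broader effect of scaling cannot be judged from their log2 fold changes. Their lower quartile lay above the upper quartile of aleurone features by 2.65 in R1-sc and 4.21 in r1-m3. They were picked for large positive changes in the same comparison, so such a gap was set in advance. With library totals without TMM factors, 25 of the 29 and 27 of the 36 were still called higher. For the general rise scaling cannot be told apart, since the difference of medians, -0.19, comes from members that go both ways. By camera the starchy endosperm features lay above others in R1-sc aleurone (adjusted p = 0.00404) and R1-sc minus R1-g starchy endosperm (0.00202), but not in r1-m3 aleurone (0.133). Under fry the adjusted p was 0.0048, 0.598 and 0.000211 in the same order, so this pattern depends on the test. A spread estimated over both compartments that is too small for these features in the aleurone stays open, since 3 of 26 and 0 of 29 tested were called with the 6 aleurone libraries alone, where edgeR called only 5 and 0 features of any kind (1505 of the second comparison at an unadjusted p under 0.05, 1212 with DESeq2), which left the test no other outcome. A difference between the genotypes stays open and was not tested further.

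Features called between genotypes in the aleurone lay closer together in feature number than shuffled calls: 12 of 112 had another within 10 numbers against a mean of 5.01 in 10000 shuffles (permutation p = 0.0342), and 35 within 50 numbers against 22.2 (0.0165). Linkage or tandem copies may explain this, but the test counted neighbours anywhere and did not look near the R1 locus. At an adjusted p under 0.01, 2 of 48 had one within 10 numbers against a mean of 0.937 (permutation p = 0.379) and 4 within 50 against 4.28 (0.642), too few to decide, as were the 14 calls in the starchy endosperm. The IDs were used as numbers only, because the positions in the build of the counts were not available, and linkage and tandem copies were not separated.

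Other splits of the same 6 libraries number 10 per comparison, too few for a share under 0.05. Between compartments the real splits gave 1784, 2579 and 1788 calls in R1-g, R1-sc and r1-m3, and the highest of the others was 0 in each with edgeR. For r1-m3 aleurone, only the real split keeps replicate 3 with replicates 1 and 2, whose features it holds. Other splits part them and widen the spread, so a gap was favoured in advance there and does not decide on chance. In the aleurone the real count and the highest other were 76 and 44 (R1-sc minus R1-g), 56 and 3 (r1-m3 minus R1-g) and 32 and 7 (r1-m3 minus R1-sc). In the starchy endosperm they were 10 and 13, 4 and 1, and 6 and 8, and in the first and last of these 2 of the 10 splits gave as many calls, the real one included; in each of the other comparisons named here it was 1 of 10.

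Replicates 1 and 2 of r1-m3 aleurone had 16789 to 16993 features detected, above the 13410 to 15329 of the R1-g and R1-sc aleurone libraries, and after thinning to equal depth 16631 to 16849 against 13265 to 15240.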
